A study of Caenorhabditis elegans with 10 samples.

How the data were processed

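The samples were whole Caenorhabditis elegans animals: wild-type eggs, L1, L2, L3 and L4 larvae, adults, dauer larvae and mixed-stage animals, and adults of the glp-4(bn2) strain. Poly(A) RNA was profiled by 3P-Seq, per the labels' protocols. The deposited tag files hold whole-number counts of tags for each distinct aligned interval and strand, 1 file per run, with no normalization. The genome build was ce6, per the file headers. Reads were aligned with Bowtie, per the submitters' processing notes. Its version, its settings and any filter on tags were not given in the sources used here. A deposited table lists 3′ UTRs with their stop codon side, cleavage site, length in bases and sequence. The authors joined 3P-Seq sites to annotated protein-coding stop codons to make it, and removed or reassigned some sites by hand, per the file headers. Its sites matched the coordinates of the ce6 tag files.

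Each group had 1 library. The mixed-stage sample was sequenced in 2 runs, which were compared with each other and then summed and counted once. The sample groups, the comparisons, the gene lists, the size rules, the rule for named genes and most alternative settings were fixed before the data were examined. The comparisons were glp-4 adults against wild-type adults, dauer against L3, egg against L1, and L4 against adult.

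The last base of a tag before the tail was taken as its cleavage position. A tag was assigned to the nearest listed site on its strand within 10 bases, and the tags of a gene were the sum over its listed sites. Between 67.2% and 71.8% of the tags of a library were assigned. Tags elsewhere, including mitochondrial tags, entered no ratio, so reported levels cover the listed sites of protein-coding genes only. Because tags come from strand-specific 3′ ends, overlapping genes on opposite strands were counted apart. The table identifies genes by Entrez number. Symbols came from a RefSeq gene table of assembly WBcel235, which matched 16014 of 16259 genes. The other 245 genes are written with their Entrez number. That assembly differs from ce6, so it served only for names and for which genes neighbour each other, and none of its coordinates is given. All coordinates are ce6 positions counted from 1.

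Levels were expressed as CPM, counts per 1000000 tags assigned to genes. Ratios between libraries were log2 ratios with a pseudocount of 1 CPM. A gene was measured when its higher library held at least 50 tags. It was called higher or lower when the log2 ratio was at least 2 in size, which is 4-fold. Exact conditional binomial 95% intervals were computed for the ratio of tag counts. For a gene with 0 tags in a library, the fold was bounded with a floor of 3 tags in that library. No p-value was computed, since no group had a replicate, and no difference between groups has a replicate check. Tags are PCR products without molecular identifiers, so intervals and floors cover counting error only. The floor of 3 tags corresponded to between 0.719 and 3.01 CPM.

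The 18 gene lists were P granule and germline RNA regulation; eggshell and oocyte; meiosis and synaptonemal complex; sperm; vitellogenins; zygotic embryonic regulators; core histones; cuticle collagens; cuticlins and moulting; dauer and stress resistance; glyoxylate, gluconeogenesis and trehalose; heterochronic; ribosomal proteins; cell cycle and DNA replication; muscle; intestine; neurons; and the mitochondrial respiratory chain. For each list the median log2 ratio over all members in the site table was given, with an order-statistic 95% interval. Its percentile was taken among 10000 random lists of the same size matched on mean expression in 20 bins. This percentile describes these libraries and is not a test of the conditions. List medians were also computed without the pseudocount, without members at 3 tags or fewer in both libraries, and with members at 0 tags placed at the floor of 3 tags. Below, these changes together are called 0-tag members at the floor. Members of the msp, his, vit, col and act families are uncertain, because near-identical copies can share reads. The core histone list was taken by the his symbol, so it also holds the linker histone gene his-24. Only 30 of its 72 genes are in the site table.

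Genes named in the text were the 10 with the largest log2 ratio each way among genes with at least 100 tags in the higher library, with at most 2 of a symbol prefix per direction. In addition, the 2 to 4 members of each list with the most tags were named, as was glp-4 itself. A stage peak was a gene with at least 50 tags in a stage and at least 4 times the level, after adding the pseudocount, of every other wild-type stage. For peaks, the 5 genes per stage with the largest ratio were eligible, from those with at least 100 tags and with at most 2 of a symbol prefix. For site use, the 8 genes with the largest share difference and at least 100 tags in both libraries were eligible.

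For alternative site use, sites holding at least 5% of the tags of a gene over all libraries were kept in genes with at least 2 such sites. The share of each site was given with an exact Clopper-Pearson 95% interval. A gene passed when it had at least 50 tags in both libraries, a share difference of at least 30 percentage points, and intervals that did not overlap. Tag-weighted UTR length was the mean length over the sites of a gene, weighted by tags, in genes with at least 50 tags in every library. The hexamer AAUAAA and its 18 variants with 1 base replaced were searched in the 40 bases upstream of each site. The plan was to run this search only with a genome of the build of the files. It was run on the sequences in the deposited site table instead, so sites of UTRs under 40 bases were left out. Opposing genes were counted as overlapping when the UTR of a plus-strand gene and that of a minus-strand gene crossed at their ends.

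Scripts were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The rules were tested on simulated counts for 16259 genes drawn at the depth of each pair of libraries. These counts held counting error only, with no PCR or biological spread. Changed genes were expected to hold at least 50 tags in both libraries, and totals were corrected for the changes that had been set. The real data met none of these conditions by design, so the passing rates below apply to the simulated setting. For each of the 4 comparisons, all 40 genes set to 6-fold, all 40 set to 8-fold and all 40 set to 16-fold passed, and none of the 40 set to 2-fold did. Of 40 genes set to 3-fold, 0 passed in glp-4 against adult, 1 in dauer against L3, 1 in egg against L1 and 0 in L4 against adult. No unchanged gene passed in any comparison (0 of 3826, 4512, 4672 and 4304, in the same order). The intervals held the true ratio for 95.6%, 95.8%, 96.0% and 96.1% of genes. Site shares moved by 45 points passed in all simulated genes of 3 comparisons and in 99.0% of those of egg against L1, and no unmoved share passed.

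Alternatives were median-of-ratios size factors or all tags of the file as the scale, a pseudocount of 5 CPM, minimums of 20 and 200 tags, and counting each distinct tag start and end once. They also included other counterpart stages, a thinned mixed-stage run, near-identical families left out, stricter peak and site rules, a 20-base assignment window, merging of sites within 40 bases, and other motif and overlap settings. The distinct-position alternative kept the minimum of 50 on tags. Size factors shifted the median log2 ratio of all measured genes by 0.35 for glp-4 against adult, −0.26 for dauer against L3, 0.24 for egg against L1 and 0.17 for L4 against adult. Ratios are reported on the total-tag scale, and these shifts apply to each of them.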

Results

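The data were 3P-Seq libraries of the nematode Caenorhabditis elegans. 3P-Seq (poly(A)-position profiling by sequencing) reads the bases just upstream of the poly(A) tail, so each tag marks a cleavage site at the 3′ end of an mRNA. The 9 samples were wild-type eggs, L1 to L4 larvae, adults, dauer larvae, mixed-stage animals and glp-4(bn2) adults, with 1 library each. Dauer is the arrested, stress-resistant alternative to the L3 stage, and glp-4(bn2) is a temperature-sensitive strain that forms few germ cells at restrictive temperature. The labels give no growth temperature. The adult library held 1390680 tags, L2 2493709, L1 3073726, L3 3525167, glp-4 adults 3575074, L4 3703769, dauer 3939265, egg 4439708 and mixed stage 5848905. Tags away from listed genes and off the mitochondrial genome made up 9.50% of the dauer and 7.98% of the mixed-stage library, against 2.88% to 5.52% in the others. Mitochondrial tags ranged from 2.38% in mixed stage to 6.37% in egg.

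The 2 runs of the mixed-stage sample held 2756965 and 3091940 tags and give the noise between runs of 1 sample. None of 4172 measured genes passed the 4-fold rule between them, and the median size of the log2 ratio was 0.11. The chi-square per gene was 1.2 over 5557 genes between runs, against 51 to 298 in the 36 pairs of groups. No member of any list passed the 4-fold rule between the runs. Percentiles of list medians among matched random lists still ran from 0.75 for dauer and stress resistance genes to 97.54 for neuron genes. The medians themselves were small, at −0.14 and 0.064. An extreme percentile can therefore arise between runs of 1 sample, so percentiles below are to be read with the size of the median. Spread between separately prepared libraries and biological spread between animals or cultures could not be measured. The chi-square range between groups includes both.

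Germline, vitellogenin and cuticle genes varied most plainly across the stages. The vitellogenins, which encode yolk proteins made by the adult intestine, had a median level (log2 of CPM plus 1, CPM being counts per 1000000 assigned tags) of 10.87 in adults and 10.83 in glp-4 adults, against 2.45 in L3. Sperm genes were at a median of 5.60 in L4 and 4.0 in adults, and at 0.00 in eggs, in each stage from L1 to L3 and in glp-4 adults. Eggshell and oocyte genes had medians of 6.16 in eggs and 5.92 in adults, against 0.65 in glp-4 adults. Cuticle collagens peaked at 5.04 in L4, and cuticlin and moulting genes at 4.95 in L3. Heterochronic genes, which time larval development, had medians of 4.82 in eggs and 2.16 in adults.

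**Figure D1:**
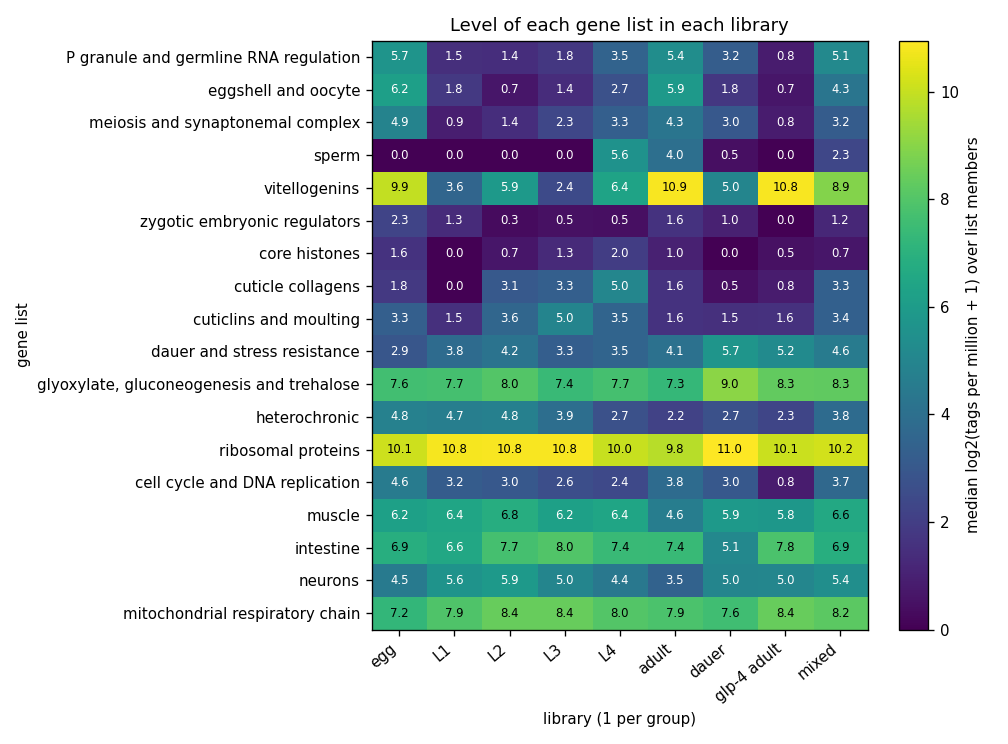
Median level of each fixed gene list (18, vertical axis) in each library (horizontal axis), as log2 of CPM plus 1 over the members of the list, with 1 library per group and no error bars. Sperm genes stand at 5.60 in L4 and 4.0 in adults, and vitellogenins at 9.95 in eggs, 10.87 in adults and 10.83 in glp-4 adults.

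The contrast of glp-4 adults with wild-type adults shows which mRNAs differ between the strains. With 1 library each, loss of germ cells cannot be told apart from other differences of strain or of growth temperature. The glp-4 gene itself (Entrez 173224, chromosome I) had 29.2 CPM in the mutant and 26.1 in wild type, a 1.12-fold difference (95% interval 0.708 to 1.82). The bn2 lesion is a point change, so these 3′ tags do not check the label. Genes of the germline were lower in the mutant. Of 11 measured P granule and germline RNA regulation genes, 10 were lower, with pos-1 146-fold lower (73.6 to 341) and puf-5, an oocyte RNA-binding protein gene, 189-fold lower (86.1 to 517). The helicase gene cgh-1 was 5.40-fold lower (4.94 to 5.91), and the Argonaute gene csr-1 was at 1.69-fold lower, inside the rule. All 14 measured sperm genes were lower, including msp-33 (major sperm protein, at least 137-fold) and msp-36 (446-fold, 78.9 to 17700). All 9 measured cell cycle and DNA replication genes were lower, with pcn-1 30.3-fold lower (21.5 to 43.8) and mcm-4 37.8-fold lower (21.1 to 74.5). So were 6 of 8 eggshell and oocyte genes, among them egg-1 (214-fold) and cpg-2 (182-fold), and 3 of 4 meiosis genes, among them htp-1 (41.4-fold, 31.3 to 55.7). In the eggshell list perm-4 was at 2.44-fold higher in the mutant (2.02 to 2.97).

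The median log2 ratio was −2.62 for P granule, −3.0 for eggshell, −2.98 for meiosis, −3.23 for sperm and −3.08 for cell cycle genes, each at percentile 0 of matched random lists. With 0-tag members at the floor, these medians were −4.76, −4.96, −4.07, −4.91 and −4.39. That setting also leaves out the pseudocount and members at 3 tags or fewer in both libraries. Of the members kept, those at 0 tags in 1 library were 1 of 24, 3 of 12, 3 of 16, 18 of 36 and 3 of 20. Neuron genes had a median of 0.90 (0.45 to 1.60, percentile 100), with 4 of 15 higher and none lower. Muscle genes had a median of 1.07 (0.08 to 1.36, percentile 99.98), with 2 of 18 higher and none lower, and held 0.816% of tags in the mutant and 0.767% in wild type. The median levels of both lists were lower in wild-type adults than in any other library. The neuropeptide genes flp-14 (6.54-fold, 4.98 to 8.74) and flp-1 (6.63-fold, 3.94 to 12) were higher in the mutant. Troponin I gene unc-27 was at 3.77-fold higher, whereas mlc-3 was at 1.32-fold lower and tba-1 at 2.5-fold lower. Of the dauer and stress resistance genes, 5 of 13 were higher and 1 lower (median 0.67, percentile 99.6). In that list lea-1 was 30.04-fold lower (25.5 to 35.6), mtl-1 at 2.89-fold higher and dct-16, the gene with the most tags in either library, at 2.0-fold lower. Vitellogenins had a median of −0.11, which becomes 0.26 with size factors, and none of 4 passed the rule. Intestine genes had a median of 0.15 with 1 higher and 2 lower of 18, cpr-1 being 4.12-fold lower and spp-5 at 1.90-fold higher.

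The other lists had few calls in this pair. Mitochondrial respiratory chain genes had a median of 0.42 (0 higher and 2 lower of 30), ribosomal proteins 0.17 (1 and 1 of 55), glyoxylate, gluconeogenesis and trehalose genes 0.13 (0 and 0 of 11) and heterochronic genes 0.19 (1 and 0 of 4). Cuticle collagens had a median of 0.00 (1 and 5 of 33, or −0.75 with 0-tag members at the floor), core histones 0.00 (0 and 1 of 6) and cuticlins −0.34 (0 and 0 of 1). Zygotic embryonic regulators had a median of −0.50 (0 and 0 of 3), which was −1.91 with 0-tag members at the floor and 1.02 over the 3 measured members. Over measured members only, the heterochronic median was 1.03, that of dauer and stress genes 1.34 and that of the single cuticlin 0.80. Among single genes, the largest ratios in the mutant's favour were those of cpr-2, a cathepsin B-like protease gene (at least 44.9-fold), scl-5 (156-fold, 53.4 to 759) and mbug-1 (116-fold, 49.7 to 359). C17F4.7 reached 5736 CPM, 82.9-fold higher (65.5 to 107). The lysozyme gene ilys-3 was 37-fold higher (18.7 to 86.1) and the small heat shock gene hsp-16.41 at least 15.1-fold higher. The most strongly lower were msd-4 (428-fold, 145 to 2080), the glycogenin gene gyg-2 (at least 170.0-fold), F14H3.6 (390.2-fold), trcs-1 (257-fold), vet-2 (533-fold, 94.6 to 21159) and the cyclin B gene cyb-1 (502-fold, 89.1 to 19939).

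In all, 265 genes were higher and 507 lower of 3859 measured. Size factors gave 403 higher and 395 lower, so higher genes made up 50.5% of the calls against 34.3% on the total-tag scale. Counting distinct tag positions gave 75 higher and 139 lower, and against L4 instead of adults vet-2 stood at 0.47 and 1059 genes were lower.

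**Figure D2:**
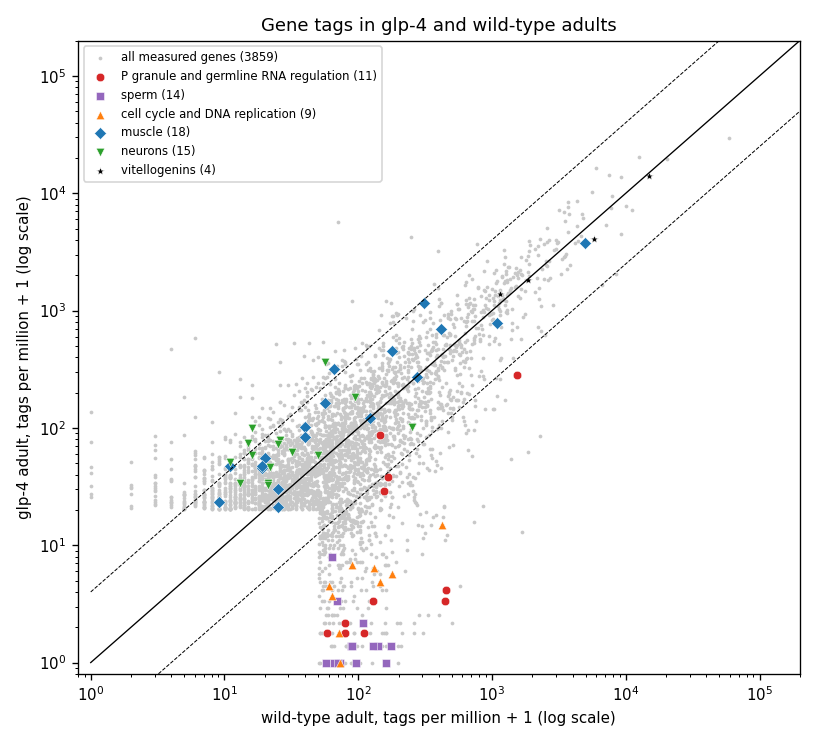
CPM plus 1 of each gene with at least 50 tags in either library, in wild-type adults (horizontal, log scale) and glp-4 adults (vertical, log scale), with 1 point per gene, a solid line at equality and dashed lines at 4-fold. P granule (11), sperm (14) and cell cycle (9) genes lie below the lower dashed line except csr-1, most neuron (15) and muscle (18) genes lie above equality, and 4 vitellogenins lie near equality.

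Dauer larvae differed from L3 larvae, their counterpart in continuous growth, in cuticle, stress, intestine and muscle genes. Cuticle collagens, the structural proteins of the cuticle, were lower in dauer for 61 of 70 measured genes and higher for 7, with a median of −2.68 (−3.34 to −1.78, percentile 0), or −3.99 with 0-tag members at the floor. Collagen col-12 was 105-fold lower (86.2 to 129) and col-17 2034-fold lower (563 to 16799). Cuticlin and moulting genes were lower for 12 of 14 and higher for none (median −3.05, percentile 0). The cuticlin gene cut-2 had 4.16 CPM in dauer and 7509 in L3, an 1806-fold difference (1009 to 3619). Of the dauer and stress resistance genes, 6 of 14 were higher and 1 lower (median 1.32, 0.56 to 2.31, percentile 99.97). The small heat shock gene hsp-12.6 had 2639 CPM in dauer and 1 tag in L3, a 6529-fold ratio (1171 to 257908). The linker histone gene hil-1 was 109-fold higher (63.7 to 206), and dct-16 was 22.2-fold lower (21.3 to 23.1).

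Intestine genes were lower for 8 of 19 and higher for 2 (median −1.85, percentile 0), the protease gene cpr-5 being 97.3-fold lower (76.8 to 125) and the actin gene act-5 4.89-fold lower. Muscle genes were lower for 9 of 22 and higher for 2 (median −1.49, −2.59 to 0.23, percentile 0), with the tropomyosin gene lev-11 11.8-fold lower (10.0 to 14.1). Neuron genes were higher for 5 of 17 and lower for none (median 0.60, percentile 90.7), with flp-14 8.20-fold (7.44 to 9.07) and flp-1 11.2-fold higher (9.13 to 13.8). Mitochondrial respiratory chain genes had a median of −0.81 (percentile 0.050) with 1 of 30 lower. In the heterochronic list 3 of 7 were higher and 3 lower (median −0.16, or −0.86 without members at or under the floor and 0.87 over measured members). The nuclear receptor gene daf-12 was 5.29-fold higher (4.32 to 6.53), the period homologue lin-42 105-fold lower (58.4 to 211) and blmp-1 6.16-fold lower (4.35 to 8.94). The RNA-binding protein gene lin-28 was 4.45-fold higher (3.52 to 5.68) than in L3, but stood at a log2 ratio of −0.62 against L2.

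All 4 measured vitellogenins were higher in dauer than in L3 (median 2.55, percentile 99.8), vit-6 by 5.96-fold (4.84 to 7.39) at 253 CPM. This direction depended on the counterpart, because vit-2 was at −2.23 and vit-5 at −0.12 against L2, and vit-6 at −1.60, vit-1 at −0.14 and vit-2 at −1.49 against L4. P granule genes had a median of 0.65 (1 higher and 0 lower of 10), meiosis genes 0.68 (0 and 0 of 5) and glyoxylate, gluconeogenesis and trehalose genes 0.62 (2 and 0 of 11), with the aconitase gene aco-2 at 3.75-fold higher. Eggshell genes had a median of 0.03 (0 and 0 of 1, that gene at 1.75), zygotic regulators 0.00 (0 and 0 of 3, or 1.48 over measured members), core histones −0.02 (0 and 3 of 8), ribosomal proteins −0.05 (0 and 0 of 55) and cell cycle genes 0.00 (1 and 0 of 9), cye-1 being 4.84-fold higher. No sperm gene had enough tags to be measured. With 0-tag members at the floor the core histone median was −2.39, and the family is uncertain.

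The largest single ratios in favour of dauer were those of F14F9.2 (at least 1631-fold), scl-12 (at least 1457-fold), C16C4.17 (at least 796-fold), the glucuronosyltransferase gene ugt-37 (at least 753-fold) and scl-13 (at least 720.1-fold). F16B4.5 reached 5736 CPM in dauer, 591-fold above L3 (397 to 923). On the lower side stood F41F3.3 (1875-fold, 803 to 5777), K02E11.10 (2845-fold), H23N18.5 (at least 992-fold), ZK180.5 (641-fold), the ground-like gene grl-16 (at least 457-fold) and the lipase gene lips-6 (595-fold). In all, 775 genes were higher and 780 lower of 5334 measured. Counting distinct positions gave 174 and 380, and of the genes called here 403 higher and 482 lower were also called against L2.

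Eggs were compared with L1 larvae to set the time before hatching against the time after it. Maternal and germline genes were higher in eggs. P granule and germline RNA regulation genes were higher for 17 of 21 measured (median 3.34, 2.61 to 4.47, percentile 100), with pos-1 117-fold (91.0 to 154), spn-4 106-fold (79.8 to 145) and puf-5 67.8-fold higher (55.2 to 84.2). All 12 measured eggshell and oocyte genes were higher (median 4.65, percentile 100), the eggshell proteoglycan gene cpg-2 by 334-fold (143 to 1029.9). Meiosis genes were higher for 12 of 13 (median 3.22, percentile 100), htp-1 by 29.5-fold. All 5 measured vitellogenins were higher (median 6.66, percentile 100), and vit-6, at 26449 CPM, was the most abundant gene in eggs and 121-fold above L1 (110 to 133). Cell cycle genes were higher for 6 of 14 (median 1.27, percentile 100), rnr-2 by 5.09-fold.

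Cuticle genes were also higher before hatching. Collagens were higher for 35 of 50 and lower for 1 (median 0.78, or 2.41 with 0-tag members at the floor), col-20 by 78.7-fold (64.9 to 96.4). Cuticlin and moulting genes were higher for 7 of 8 (median 1.54, percentile 99.95), cut-2 by 47.4-fold (42.5 to 52.9) and noah-2 by 104-fold (60.8 to 196). Neuron genes were lower for 6 of 17 and higher for none (median −1.65, −1.93 to −0.70, percentile 0), flp-9 by 6.74-fold (6.12 to 7.43). Among zygotic embryonic regulators 2 of 5 were higher (median 0.10, or −0.09 over measured members), tbx-9 by 195-fold (34.7 to 7728) and pal-1 by 6.98-fold (5.09 to 9.78). Heterochronic genes were higher for 3 of 12 (median −0.16), lin-42 by 8.08-fold, and lin-28 was at 3.31-fold lower (2.94 to 3.73). The late embryogenesis abundant gene lea-1 was 38.3-fold higher (31.1 to 47.8) in a dauer and stress list with 3 of 10 higher (median 0.00). Mitochondrial respiratory chain genes had a median of −1.0 (percentile 0.12; 1 higher and 0 lower of 30), atp-2 being at 3.03-fold lower. Ribosomal proteins (−0.46; 1 and 1 of 54), glyoxylate, gluconeogenesis and trehalose genes (−0.57; 0 and 1 of 10), intestine (−0.37; 1 and 1 of 16) and muscle (−0.27; 1 and 1 of 22) had smaller medians, and no sperm gene was measured. Core histones had a median of 0.34 (percentile 99.8; 2 and 1 of 8), or 1.06 with 0-tag members at the floor. The tags of the list went the other way, at 0.341% of the total in eggs and 0.596% in L1, so it gives no clear direction.

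The largest single ratios were W02D9.7 (at least 211-fold higher in eggs), ZK813.1 (270.0-fold, 202 to 369, at 5710 CPM), ZK813.3 (252-fold), C08F11.12 (248-fold), ule-3 (213-fold) and Y73B3A.1 (at least 165-fold). On the side of L1 were C25F9.11 (76.1-fold, 44.2 to 144), srw-86 (57.2-fold), nssp-76 (109.9-fold, 29.9 to 916) and F45D3.3 (26.6-fold, 21.6 to 33.1). In all, 877 genes were higher and 477 lower of 5225 measured. Counting distinct positions gave 465 and 65.

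L4 larvae, the last larval stage, were compared with adults. Collagens were higher in L4 for 65 of 89 measured genes and lower for 7 (median 2.54, 1.87 to 3.17, percentile 100), col-12 by 15.1-fold (14.2 to 16.1) at 16445 CPM and col-88 by 242-fold (66.7 to 1996). All 7 measured cuticlin and moulting genes were higher (median 2.55, percentile 100), cut-2 by 66.7-fold (39.7 to 122). Sperm genes were higher for 10 of 35 and lower for none (median 1.22, 0.76 to 1.75, percentile 100), msp-31 by 7.51-fold (6.29 to 9.04) and msp-10 by 5.45-fold (4.58 to 6.53). Counted by distinct positions msp-10 stood at −0.021. Muscle genes were higher for 4 of 20 (median 1.63, percentile 100), lev-11 by 9.52-fold (7.94 to 11.5), and neuron genes for 5 of 15 (median 1.16, percentile 99.98), flp-9 by 7.12-fold. In the heterochronic list 2 of 5 were higher (median 0.47, or 1.08 over measured members), lin-42 by 16.5-fold (9.12 to 33.2).

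Vitellogenins were lower in L4 for all 4 measured genes (median −4.59, percentile 0), vit-5 by 81.8-fold (59.0 to 117), vit-1 by 71.9-fold (62.7 to 82.8) and vit-6 by 19.5-fold. Cell cycle genes were lower for 6 of 9 (median −1.43, percentile 0), pcn-1 by 4.89-fold, as were 4 of 8 eggshell genes (median −1.53, percentile 0), cpg-2 by 5.10-fold, and 4 of 13 P granule genes (median −1.10, percentile 0), pos-1 by 5.83-fold. Meiosis genes had a median of −0.99 with none of 6 past the rule. The dauer and stress list had 2 of 9 lower (median −0.21, or −1.09 over measured members), with the metallothionein gene mtl-1 5.67-fold lower (5.05 to 6.38). Ribosomal proteins (0.23; 0 and 0 of 55), intestine (−0.25; 2 higher and 1 lower of 16), core histones (0.47; 2 and 0 of 7) and zygotic regulators (−0.16; 0 and 1 of 3, or 0.30 over measured members) had small medians. Those of glyoxylate, gluconeogenesis and trehalose genes (−0.05; 0 and 0 of 11) and the respiratory chain (−0.02; 0 and 0 of 29) become 0.12 and 0.15 with size factors, and the latter 0.05 with 0-tag members at the floor. Among single genes, col-91 (at least 116-fold), dbd-20 (162-fold, 99.4 to 283), abu-1 (125-fold) and abu-7 (113-fold, 84.2 to 155) led the genes higher in L4. The Skp1-related genes skr-8 (at least 186-fold) and skr-14 (at least 139-fold), vet-2 (at least 182-fold) and the insulin-like gene ins-19 (209-fold) led those lower. In all, 688 genes were higher and 166 lower of 4455 measured. Counting distinct positions gave 301 and 28.

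Tags of 630 of 6942 genes peaked in a single wild-type stage. Dauer had 240 such genes, L4 198, egg 160, adult 12, L3 8, L1 6 and L2 6. In dauer they were led by C52E2.2 (219.5 times the next stage), F14F9.2 (152 times), F16B4.5 (133 times) and scl-12 (118 times). Of genes with at least 50 tags in dauer, 5.42% peaked there. The peaks included 12 of 22 such ugt genes, which encode glucuronosyltransferases, 9 of 47 nlp neuropeptide-like genes, 7 of 39 nssp genes and 6 of 55 nuclear receptor nhr genes. These families were counted after the values were seen, and no enrichment was tested. In L4 the peaks were led by col-88 (161 times) and col-49 (105 times) and included 15 collagens and 9 sperm genes. In egg they were led by the collagen col-165 (57.1 times) and Y73B3A.1 (51.7 times) and included 8 P granule and 4 eggshell genes. Adult peaks were led by C10G8.4 (7.4 times) and ule-2 (6.81 times), both of which had more CPM in glp-4 adults (1754 and 940.2) than in wild-type adults (1286 and 662). L3 peaks were led by oac-29 (45.8 times), L1 by R05H11.2 (7.75 times) and L2 by idpp-15 (6.59 times). Requiring 8 times left 229 genes.

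The deposited table lists 23929 cleavage sites in 16259 genes, of which 5093 (31.3%) have at least 2 sites, and T19D12.2 has 13. The median 3′ UTR was 133 bases (quartiles 72 and 252). UTRs of genes with a single site had a median of 102 bases, against 236 at distal and 133 at proximal tandem sites, which follow the same stop codon. By the site with the most tags, the median over all genes was 118 bases. Heterochronic genes had the longest UTRs of the lists, with a median of 932 bases (697 to 1392, percentile 100). P granule (287.5 bases), muscle (280.0), cuticlin and moulting (240) and cell cycle genes (222) were also at or above percentile 99. Ribosomal protein (50 bases), sperm (52) and collagen genes (70) were at percentile 0, and intestine genes (87.5) at percentile 0.60. Keeping sites with at least 5% of the tags of a gene left 20.9% of genes with at least 2 sites.

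Tag-weighted UTR length over 1542 genes had a median between 146 and 147 bases in each of the 9 libraries. Between eggs and L1 the median difference per gene was −1.19 bases (−1.56 to −0.86) over 1041 genes with at least 2 sites, with 639 shorter and 322 longer in eggs. In the other comparisons the median difference was at most 0.10 bases in size.

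Single genes switched between sites by far more than this. In glp-4 against wild-type adults 13 of 290 genes passed the site rule, 12 of them toward distal sites. At a share difference of 20 points, 33 passed, 11 of them toward proximal sites. The proximal site of F18E3.13 (ce6 chromosome V, 7416493, 80-base UTR) took 23.6% of tags in the mutant (17.2 to 31) and 85% in wild type (77.3 to 90.9). The proximal site of vha-2, a vacuolar ATPase gene (chromosome III, 9782999, 354-base UTR), took 20.02% (17.8 to 22.4) and 74.9% (70.9 to 78.5), and that of lea-1 (chromosome V, 10023095) 29.7% and 79.6%. The proximal site of the ATP synthase gene atp-2 (chromosome III, 5230272, 79-base UTR) took 10.9% and 42.5%. In dauer against L3, 30 of 480 genes passed, 15 in each direction. The gene dur-1 used its distal last exon (chromosome IV, 9921910) for 97.3% of tags in dauer (96.8 to 97.7) and 10.5% in L3 (8.65 to 12.56). The proximal site of ncs-2, a neuronal calcium sensor gene (chromosome I, 10033407, 613-base UTR), took 73.9% in dauer and 22.7% in L3.

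In eggs against L1, 32 of 472 genes passed, 26 of them toward proximal sites in eggs. The distal site of the calcium pump gene sca-1 (chromosome III, 10811787) took 22.2% of tags in eggs (18.7 to 26.1) and 78.5% in L1 (74.8 to 81.9), and that of gei-17 (chromosome I, 9100837) 62.2% and 98.6%. In L4 against adult, 6 of 319 genes passed. Cyclin B gene cyb-1 used its proximal site (chromosome IV, 10736758, 35-base UTR) for 87.1% of tags in L4 (83.0 to 90.5) and 31.4% in adults (24.7 to 38.6), the rest ending at a 423-base UTR. Between the 2 mixed-stage runs 1 of 586 genes passed. At 20 points 66, 74 and 17 genes passed in the other 3 comparisons, 33, 59 and 8 of them toward proximal sites. With at least 200 tags in both libraries, 2, 5, 6 and 1 genes passed in the 4 comparisons, in the order given.

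**Figure D3:**
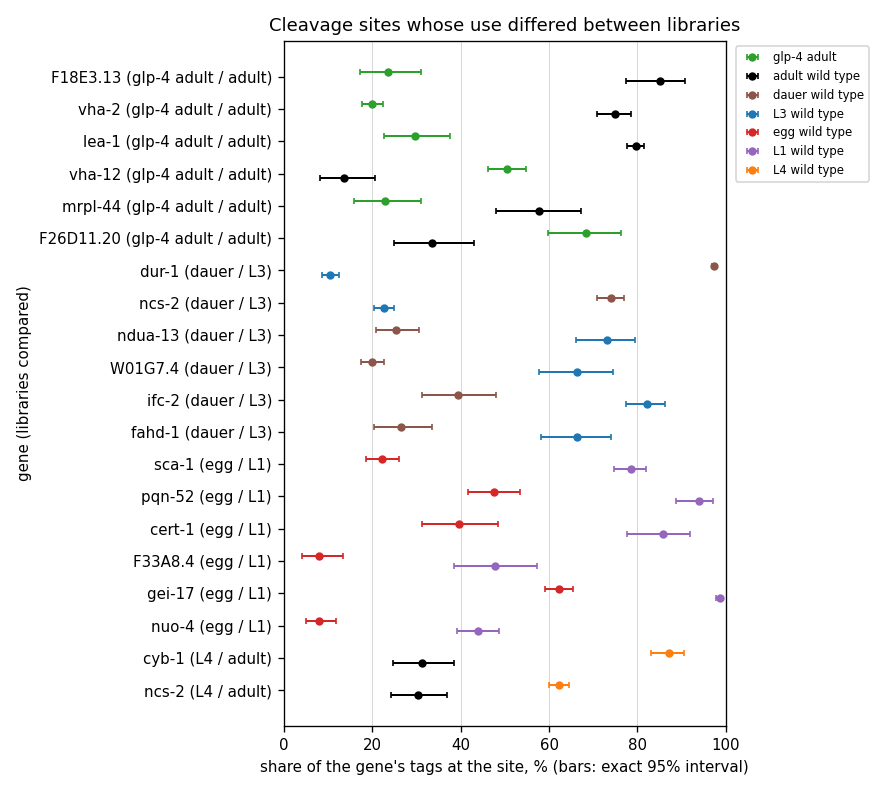
Share of the tags of a gene at the cleavage site that differed most (horizontal, %) for up to 6 named genes of each of the 4 comparisons (vertical), with a point per library and bars for the exact 95% binomial interval, 1 library per group. The dur-1 site takes 97.3% of tags in dauer and 10.5% in L3, and the cyb-1 site 87.1% in L4 and 31.4% in adults.

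The poly(A) signal hexamer AAUAAA lay in the 40 bases upstream of 42.1% of 21784 sites (41.4 to 42.7). A variant with 1 base replaced was present at 42.5%, and neither at 15.4%. In UTRs of at least 80 bases, 39.7% of sites had AAUAAA in that window, against 6.07% in the 40 bases before it. A variant without AAUAAA was in that window at 44.0% of these sites, against 27.7% in the 40 bases before it. Many variant matches are therefore found away from the site as well. The first base of AAUAAA lay a median of 19 bases before the cleavage site (quartiles 18 and 21). AAUAAA was present at 54.9% of single sites (54 to 55.9), 43.8% of distal tandem sites (42.2 to 45.4) and 16.8% of proximal tandem sites (15.7 to 17.9). Among sites with a variant and no AAUAAA, AATGAA was the most frequent, at 2178 sites (23.5%), followed by TATAAA at 1679 (18.1%), written as DNA. Sites with AAUAAA took between 59.1% of tags in eggs and 66.2% in glp-4 adults.

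**Figure D4:**
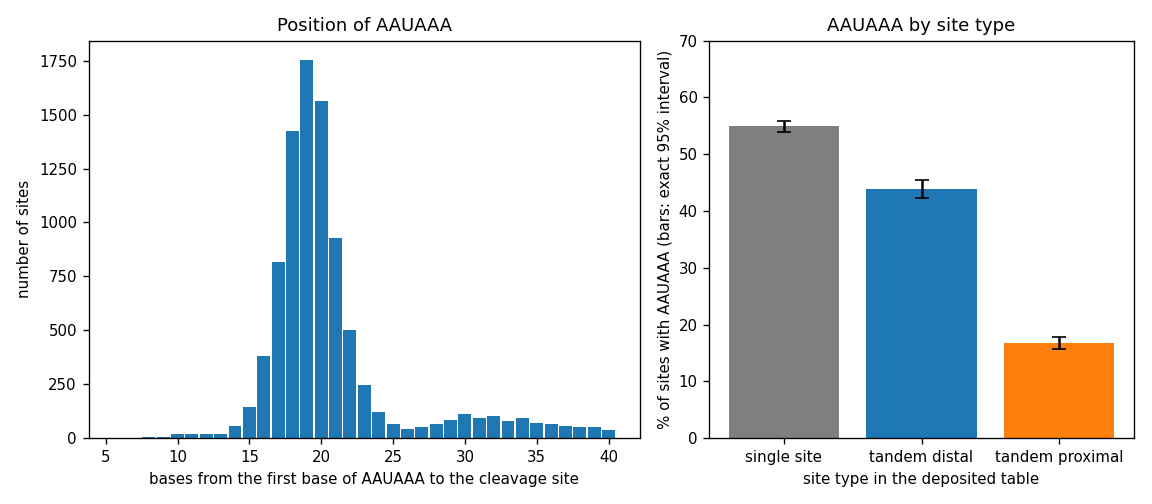
Left, number of sites (vertical) by distance in bases from the first base of AAUAAA to the cleavage site (horizontal), which has its mode at 19 bases. Right, percent of sites with AAUAAA by site type, with exact 95% intervals, at 54.9% for single, 43.8% for distal tandem and 16.8% for proximal tandem sites.

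The 3′ ends of 1265 pairs of opposing genes overlapped, involving 2528 genes (15.5% of those listed), by a median of 45 bases. The longest overlaps were 526 bases between rgs-4 and Y38E10A.22 on chromosome II (12672184 to 12672709) and 477 bases between the replication protein gene rpa-2 and M04F3.4 on chromosome I (4771350 to 4771826). By main sites, 1010 pairs overlapped, with a median of 38 bases. Among 1247 pairs with main sites within 100 bases of each other, 953 overlapped and 294 lay apart. Offsets of 10 to 19 bases occurred in 181 pairs and of 20 to 29 in 167, those of 30 to 39 in 89, and those of 40 to 49 in 121.

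**Figure D5:**
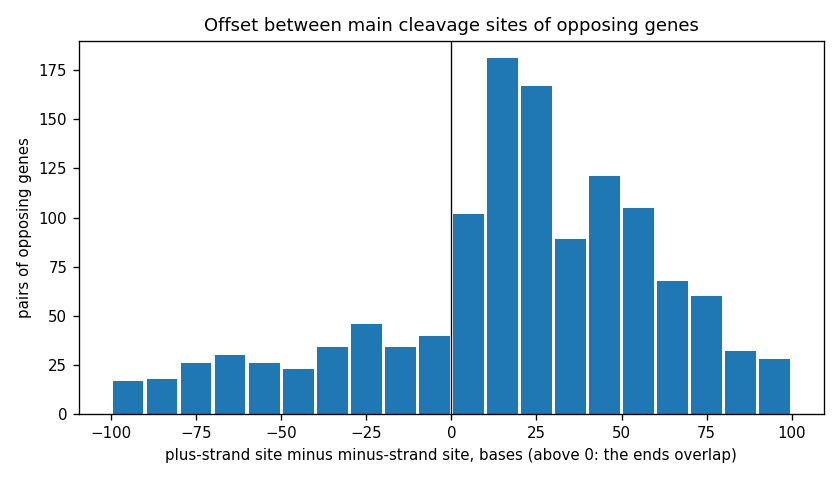
Number of opposing gene pairs (vertical) by the plus-strand main site minus the minus-strand main site in bins of 10 bases (horizontal), where values from 0 upward are overlapping ends. The counts are 167 pairs at 20 to 29 bases, 89 at 30 to 39 and 121 at 40 to 49.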

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

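The rule for tag clusters and the look at mitochondrial tags were both chosen after the libraries had been counted. The clusters below hold at least 5000 tags in a library and lie at least 200 bases from every listed site, so no comparison used them. Coordinates are ce6, and names of genes lying between the neighbours come from WBcel235. No technical or biological explanation of these clusters was tested.

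The largest cluster, with 679079 tags on the plus strand of chromosome I (4790516 to 4790674), lies between M04F3.5 and gnrr-1, where WBcel235 places the ribosomal protein genes rpl-41.1 and rpl-41.2. It was highest in dauer (26169 per 1000000 tags of the library, the unit of all levels given here) and the median of the other libraries was 21851. A cluster of 304399 tags on the minus strand of chromosome X (1504113 to 1504345) lies between F09E10.1 and toca-1, where WBcel235 places the noncoding RNA gene tts-1. It reached 25990 in the mixed-stage library, 25678 in dauer and 6885 in glp-4 adults. The median over all libraries but mixed stage was 1834. On the minus strand of chromosome V (6388925 to 6388963), 41398 tags lay between F13H6.5 and F57F4.1, and 39604 of them came from dauer (10054, against a median of 3.60 elsewhere).

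On the plus strand of chromosome II (8789672 to 8789732), between sgn-1 and F07H5.13, there were 40321 tags, with the highest level in glp-4 adults (2598). Near the end of chromosome I, after F31C3.6, the plus strand (15064801 to 15067507) held 21049 tags, with the highest level in mixed stage (991). The minus strand of chromosome II (10542330 to 10542429), between pro-1 and mnk-1, held 18200 tags, with the highest level in dauer (1525). A further 16212 tags lay on the minus strand of chromosome V (12166731 to 12166744) between C27A7.5 and ZK863.1, where WBcel235 places col-37, and 13791 of them came from mixed stage. On the plus strand of chromosome X (15434872 to 15434901), between blos-8 and mocs-1, with flp-32 between them in WBcel235, there were 7207 tags, 5016 of them from dauer. Between ints-8 and ndrr-1 on chromosome I (13464192 to 13464202, plus strand), where WBcel235 places the RNA gene rpr-1, 6075 of 6278 tags came from glp-4 adults (1699, against a median of 4.15 elsewhere). Mitochondrial tags, which no listed site covers, were at most 6.37% of a library, in eggs.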

How the results depend on the processing

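Keeping list members with at least 50 tags only, and keeping tandem sites only, were chosen after the data were seen. Each alternative changed a single choice. No paired analysis was possible because each group had 1 library. No families-left-out value exists for vitellogenins and core histones, which have no other members. Except where an alternative's construction sets the direction (a higher minimum or multiple leaves fewer genes, a lower one more, and distinct positions saturate), the cause was not tested. Depth limits the adult comparisons most, since the adult library is the smallest.

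Genes higher and lower moved as follows. In glp-4 against adult, size factors gave 403 higher, with 265 higher and 395 lower genes called under both scalings. Minimums of 20 and 200 tags gave 416 and 123 higher and 954 and 111 lower, distinct positions 75 and 139, and L4 as counterpart 1059 lower, with 111 higher and 242 lower genes shared. In dauer against L3, a minimum of 200 gave 405 and 383, and distinct positions 174 and 380. In egg against L1, a minimum of 200 gave 476 and 190, a minimum of 20 gave 743 lower, and distinct positions 465 and 65. In L4 against adult, minimums of 20 and 200 gave 1085 and 282 higher and 304 and 67 lower, and distinct positions 301 and 28.

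Called genes that reversed were vet-2 in glp-4 adults (0.47 against L4) and msp-10 in L4 (−0.021 by distinct positions). The vet-2 value rests on tags under the floor of 3 in both libraries and gives no direction. In dauer, vit-2 (−2.23 against L2, −1.49 against L4), vit-5 (−0.12 against L2) and lin-28 (−0.62 against L2) reversed. So did vit-6 (−1.60 against L4) and vit-1 (−0.14 against L4). For named genes in the 4 comparisons, distinct positions left 57 log2 ratios within their intervals, moved 305 and reversed 1, size factors left 224 and moved 139, a pseudocount of 5 CPM left 275 and moved 88, and the file total as scale left 349 and moved 14. Counterparts moved most of the ratios they were tried on: L4 left 39, moved 137 and reversed 4, and L2 left 25, moved 62 and reversed 3.

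List medians with members of at least 50 tags were, for glp-4 against adult, −5.19 for P granule, −6.64 for eggshell, −4.29 for meiosis, −6.09 for sperm, −4.82 for cell cycle, 1.02 for zygotic, 0.30 for histone and 0.12 for collagen genes. For dauer against L3 they were 1.75 for eggshell, 1.48 for zygotic, −4.21 for cuticlin and −5.47 for collagen genes, and for egg against L1 4.44 for P granule genes, 5.88 for eggshell genes, 3.69 for collagens, 4.35 for cuticlins and 0.53 for dauer and stress genes. For L4 against adult they were 0.30 for zygotic genes and 3.94 for collagens. Without near-identical families the collagen medians, which then rest on few genes, were −1.0, −5.56, 1.93 and 3.78 in the 4 comparisons. Size factors moved ribosomal proteins to 0.53, muscle to 1.43 and the respiratory chain to 0.78 in glp-4 against adult, P granule genes to 0.45 and ribosomal proteins to −0.31 in dauer against L3, and ribosomal proteins to 0.40 in L4 against adult. In all, size factors moved 6 list medians and left 66 within their intervals.

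Stage peaks at 8 times every other stage numbered 45 in egg, 1 in L1, 0 in L2, 1 in L3, 75 in L4, 1 in adult and 106 in dauer, 229 in all. With at least 200 tags they numbered 3 in L1, 2 in L2, 4 in L3, 67 in L4, 6 in adult and 155 in dauer, 360.0 in all, and without dauer 415 genes peaked.

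Keeping sites with at least 5% of tags gave 20.9% of genes with 2 or more sites and a median UTR of 127 bases. In 431 genes with at least 200 tags in every library, the tag-weighted median was 127 bases in egg, 128 in L1, 130.0 in L2, 129 in L3, 128 in L4 and 128 in adult, dauer, glp-4 and mixed-stage libraries. Genes past the site rule at 20 points numbered 33 in glp-4 against adult (11 toward proximal sites), 66 in dauer against L3 (33), 74 in egg against L1 (59) and 17 in L4 against adult (8). At 200 tags they numbered 2 (0), 5 (3), 6 (6) and 1 (0), and 0 between runs. With tandem sites only they numbered 8 (0) in glp-4, 19 in dauer and 14 (11) in egg, with 1 toward proximal sites in L4. With a 20-base window, 0 went toward proximal sites in glp-4, and with sites within 40 bases merged 0 passed between runs.

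With the hexamer searched 10 to 30 bases upstream, AAUAAA was at 38.5% of sites, a variant at 40.4% and neither at 21.1%. At sites with at least 10 tags these were 47.3%, 41.8% and 10.9%. Median overlap of opposing ends was 38 bases by main sites and 40 at sites with at least 10 tags.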

Other observations

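The test of germline loss as a rescaling of all somatic genes, the list that decides it, and the split of tandem sites by abundance, were chosen only after the result was seen, and so were the genes of the next sentences. Site use in some genes followed the stages. The proximal site of vha-2 took 28.2% of its tags in eggs, 26.9% in L1, 29.6% in L2, 51.7% in L3, 61.9% in L4 and 74.9% in adults, against 20.02% in glp-4 adults and 22.1% in dauer. The proximal site of F18E3.13 took between 95.3% and 99.0% from egg to L4, 85% in adults and 23.6% in glp-4 adults. The cyb-1 site that took 87.1% of tags in L4 and 31.4% in adults took 2.97% of 1112 tags in eggs. The distal exon of dur-1 took 97.3% of 5600 tags in dauer, and between 10.5% and 62.5% in the other libraries.

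Sites with more tags carried AAUAAA more often, at 54.3% of the 20% of sites with the most tags and 29.7% of the 20% with the fewest, a difference of 24.6 percentage points with intervals that did not overlap. Distal tandem sites carried it more often than proximal ones by 27 points. Position and abundance could be entangled, but the order of distal over proximal held in each of 5 groups of sites of like abundance, from 30.7% against 7.46% in the lowest to 51% against 32.6% in the highest.

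Offsets of 26 to 36 bases between opposing main sites were fewer where both sites had AAUAAA, at 5.76% of 191 pairs (2.91 to 10.1) against 11.4% of 588 other pairs (8.94 to 14.2), among offsets of 0 to 69 bases. The band is where 2 hexamers lying 19 bases before their sites would share bases, and the counts of all offsets had been seen when it was set. A candidate explanation is that hexamers on opposite strands cannot share the same bases. The difference of −5.64 points goes that way, but the intervals overlap, so these data do not decide it.

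Vitellogenin tags in eggs stood at a median log2 ratio of 6.66 above L1. Thinning the egg library to the tags of L1 gave 6.66 again, which decides nothing about depth, because CPM ratios of abundant genes hardly move when a library is thinned. Relative to adults, 4 vitellogenins had a median of −0.58 in eggs. The vitellogenin list took 3.15% of assigned tags in eggs and 2.38% in adults. Carry-over of adult somatic RNA could account for part of the tags in eggs. Another 34 genes abundant in adults, low in L1 and L4 and little different in glp-4 adults had a median egg-to-adult ratio of −1.60, which is −1.02 relative to the vitellogenins (−1.91 to −0.55). The median lies just past the bound of −1 set for carry-over and the interval reaches across it, so carry-over and RNA of the eggs themselves cannot be told apart here.

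Vitellogenins in dauer stood at a median of −5.89 relative to adults. Over the whole list the median level was 4.965 in dauer, inside the larval range from 2.445 in L3 to 6.353 in L4. For carry-over of adult somatic RNA, 27 other adult-abundant genes should stand at a like ratio, and their median differed by 0.46 (0.06 to 1.05). For whole adults mixed into the dauer sample, eggshell and oocyte genes should follow the vitellogenins, and 8 of them differed from the predicted level by a median of 0.85 (−0.29 to 2.11). Both values go with a small share of adult RNA, near 1.65% by the vitellogenins, but neither test decides it. The 27 genes were chosen as low in L1, L3 and L4, so they could be low in dauer for that reason. The eggshell and oocyte genes were predicted at a median of 2.95 CPM and observed at 7.56. The whole eggshell list differed little between dauer and L3 (median 0.03), so larval background would pass too. Transcription in dauer larvae stays open as untested.

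Muscle and neuron genes had a median log2 ratio of 0.93 in glp-4 against wild-type adults. Both lists had their lowest median level in wild-type adults, muscle at 4.648 against 5.795 in glp-4 adults and 6.425 in L4. Neuron genes stood at 3.463, 5.024 and 4.405 in the same order. L4 against the same adult library gave list medians of 1.63 and 1.16. A low wild-type adult library and a rise in the mutant cannot be told apart here. Thinning the glp-4 library to adult depth gave a muscle and neuron median of 1.0 (0.49 to 1.36), where a value below 0.5 had been predicted for depth. As in eggs, this decides nothing about depth, because CPM ratios hardly move when a library is thinned. Loss of germline tags may scale all somatic genes alike, but vitellogenins did not share the factor: the muscle and neuron median lay 1.03 above theirs (0.56 to 1.78). Of 8 such contrasts, with 3 somatic lists and a pool under 2 choices of members, each had an interval above 0. They share members, so they are not separate tests. The all-member medians of collagens and of the pool were 0.00, with only 33 of 155 collagens measured. Those contrasts restate the muscle and neuron median and cannot show whether measured somatic genes were rescaled. The lower end was under 0.5 in 4 of the 8, as for all intestine genes (0.77, 0.11 to 1.62). Rescaling behind part of the difference therefore stays open.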
